A study of Mus musculus with 3 samples.

How the data were processed

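Chromatin from i660BM cells, a mouse pro-B cell line of the C57BL/6 strain that carries a doxycycline-inducible PU.1 construct, was immunoprecipitated with a polyclonal antibody to PU.1 and sequenced (ChIP-seq). PU.1, encoded by Spi1, is a transcription factor of the ETS family used in B cells and myeloid cells. Per the labels, induction of both PU.1 libraries lasted 24 h at 70 ng/ml doxycycline, and 1 further sample was input DNA. The PU.1 libraries carry the replicate numbers 2 and 3 in their titles and are named so here. Nothing in the labels says that they came from separate cultures, so any spread between them may be technical.

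Reads were trimmed with Trim Galore, aligned with Bowtie and searched for peaks with MACS 1.4.1 on build mm10, per the submitters' processing notes. Versions of the first and second of these tools are not given in the sources used here. Each PU.1 library has its own peak list, so peaks were called per sample. A merged list of intervals for the series was analysed as well, and the way it was made is not given in the sources used here. The fifth column of each peak list holds a score given by the authors' peak caller, read here as minus 10 times the log10 of the peak's p-value, which is what that version of MACS writes. The deposited score was used only to describe, rank or filter peaks within its own list, because it depends on the depth of its library and carries no normalization between libraries. The merged list holds a score of 0 in every row and was used for positions alone. Whether the input library served as the control for peak calling is not given in the sources used here. Read depth per library was not used here.

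The lowest score was 70.0 in both lists. A score of exactly 3100 was read here as a p-value too small for the computer to hold, a reading that the sources used here do not state. Some peaks have scores slightly above it, up to 3233. In replicate 2, 2656 peaks lay at or above 3100, and in replicate 3, 11 peaks did. Ranks within this top group are therefore uncertain. A ranking that places scores of exactly 3100 above all others was added after the data were examined.

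Peaks shared by 1 bp or more were called overlapping. Shared regions were the merged intervals of both lists that hold at least 1 peak of each, and they formed the main set. Overlap was set against 100 placements of the same peaks at random on the same chromosome, between the lowest and the highest coordinate of any peak or gene there, since chromosome lengths and assembly gaps were not used here. The smallest p such placements can give is 0.0099 one-sided and 0.0198 two-sided. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Rank agreement between scores was tested with 100000 permutations across regions, which are not independent replicates.

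Genes came from a RefSeq gene table of the assembly GRCm38.p6, the same build as mm10, which gives 1 span per gene without strand or exons. Promoter-based steps planned on the transcription start site were therefore run on either end of the span, and exons and introns were not separated. Of the regions, those centred within 1 kb of an end of a protein-coding gene were classed first, then those inside a protein-coding gene, inside another gene, and intergenic. Genes were called bound where a region came within 5 kb of either end. Each of 12 gene lists, with 314 members of which 313 were matched, was tested against all other protein-coding genes with a two-sided Fisher exact test and Benjamini-Hochberg adjustment over the lists. The lists were BCR signalling, pre-BCR and recombination, B-lineage transcription factors, IL-7 and JAK-STAT signalling, MHC class II presentation, TLR and NF-kB signalling and myeloid genes, with T cell, erythroid, liver, neuron and ribosomal protein genes for comparison. These tests treat genes as units and say nothing of expression. Immunoglobulin V segments were called bound where a region came within 1 kb.

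Gene lists, the main tests and the rule for naming genes were set before the data were examined. Tests added later compare shared regions with peaks found only in replicate 2 by location, functional V segments with pseudogenes, and chromosome X with autosomes. The text names the nearest protein-coding gene of the 10 shared regions with the best mean of the ranks of score in both lists. It draws on up to 4 members per gene list with a shared region, by the same rank. The rule further always covers Spi1, Spib, Btk, Blnk, Cd79a, Cd79b, Syk, Il7r, Fcgr2b, Csf1r, Itgam, Cd22, Rag1, Igkc, Iglc1 and Iglc2. Genes named outside this rule are marked as chosen after their values were seen.

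Alternatives were a score of at least 100, reciprocal overlap of 50%, either list alone, the merged list, other windows around genes, other backgrounds and a null made by shifting peaks 10 kb. Comparisons within 10% and 1% bins of replicate 2 score, where peaks of equal score share a 1% bin, were pooled as Mantel-Haenszel odds ratios. Planned motif and 8-mer searches and the repeat filter were not run, because a genome sequence was not used here. Steps were tested on simulated data. With 48.6302% of 6169 peaks planted on the other list, 48.6084% were recovered for the replicate overlap. Over 21887 genes, all 20 members given a region were recovered for the gene list test. The added regions lay across a gene end, so this recovery was fixed in advance and checks the code alone. Of 9 lists without added regions, 0 passed an adjusted p of 0.05. Those lists were random genes set against regions placed at random, so the error rate for real lists and peaks is not given by them. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.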

Results

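PU.1 occupancy was mapped by ChIP-seq in i660BM pro-B cells, a stage at which B cell precursors rearrange their immunoglobulin heavy chain genes, after induction of PU.1 with doxycycline. Both PU.1 libraries were induced, so signal that depends on the induction is not told apart from signal that does not. The 2 PU.1 libraries gave lists of very different length. Replicate 2 had 74494 peaks covering 81.2 Mb, with a median width of 995 bp and a median score of 232. Replicate 3 had 6169 peaks covering 6.19 Mb, with a median width of 977 bp and a median score of 136. A score of at least 100 was reached by 60891 peaks of replicate 2 and 4339 peaks of replicate 3. The merged list held 49385 intervals covering 59.2 Mb. Coordinates are 1-based on GRCm38 (mm10).

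The first comparison asks how far both libraries mark the same sites. Every one of the 6169 replicate 3 peaks overlapped a replicate 2 peak (100%, exact 95% interval 99.9 to 100), against 6.14% ± 0.332 (SD over 100 random placements; permutation p = 0.0099, one-sided, the smallest the placements can give). Of the replicate 2 peaks, 6139 overlapped a replicate 3 peak (8.24%, 8.04 to 8.44), against 0.519% at random (permutation p = 0.0099, one-sided, again the smallest possible). Against peaks shifted by 10 kb, the planned second null, chance overlap was higher, at 13.6% and 1.22%. The peaks merged into 6133 shared regions covering 8.87 Mb. With at least 50% of both peaks required to overlap, 88.9% of replicate 3 peaks and 7.36% of replicate 2 peaks were matched.

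The replicate 3 peaks lay at the high end of the replicate 2 scores. Among the 10% of replicate 2 peaks with the highest scores, 5421 of 7450 had a replicate 3 peak (72.8%, 71.7 to 73.8), and in the next 10% the share was 9.20% (8.55 to 9.87). Among the 37247 peaks in the lower 50% of scores, 3 had one (0.00805%). When replicate 2 was reduced to its best 6169 peaks, all with scores of at least 1908, 80.5% of these overlapped replicate 3 and 81.1% of replicate 3 overlapped them. Across the 6133 shared regions the scores ranked together, with a Spearman correlation of 0.737 (95% interval 0.725 to 0.749; permutation p = 1e-05, the smallest the permutations can give). This correlation runs across regions, which are not independent replicates. It was 0.532 (0.506 to 0.556) over the 3555 regions with a replicate 2 score under 3100.

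**Figure D1:**
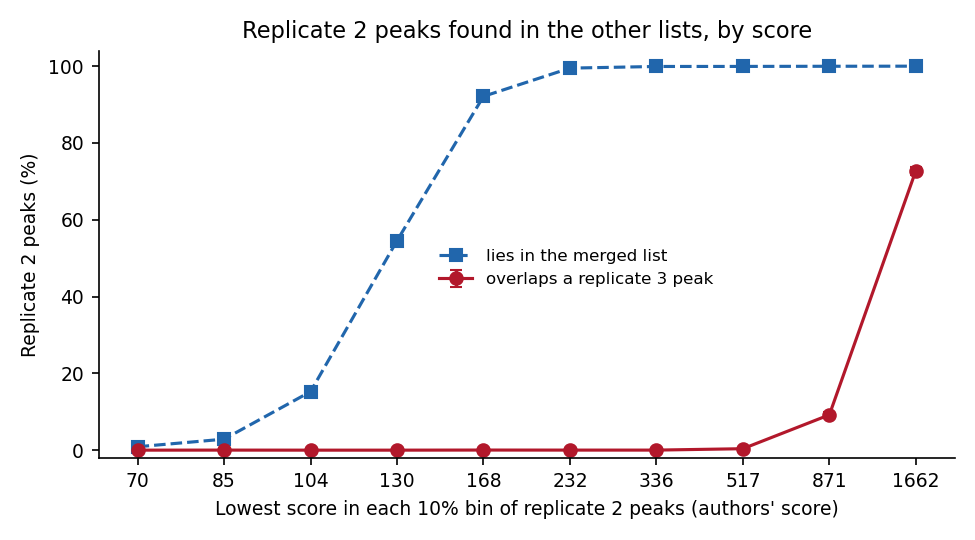
Share of replicate 2 peaks (y axis, percent) that overlap a replicate 3 peak (circles, with exact 95% intervals) or lie in the merged list (squares), over 10% bins of the authors' replicate 2 score (x axis, lowest score of each bin). The share in replicate 3 reaches 72.8% in the highest bin, while the share in the merged list is already 92.1% in the bin that starts at a score of 168.

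The merged list held peaks of both libraries. Of its 49385 intervals, 49371 held a replicate 2 peak and 6134 (12.4%) a replicate 3 peak. It contained all 6169 replicate 3 peaks and 66.5% of replicate 2 peaks, with 24964 replicate 2 peaks left outside. The share of replicate 2 peaks inside it was 0.886% in the lowest 10% by score, 54.5% in the bin from 130 to 168 and 99.99% in the highest. Both ends equalled those of a peak of either list in 5095 intervals (10.3%).

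The naming rule picks shared regions by mean rank, and its order at the top is limited by the score ceiling. The best mean rank fell to a region inside LOC108168726 (chromosome 2, 3605005 to 3606041; score 3223 in replicate 2 and 431 in replicate 3) and to a region inside Chchd3, a gene of mitochondrial cristae organisation (chromosome 6, 32799195 to 32800353; 3233 and 341). The list went on with an intergenic region 44.5 kb from Il6, which encodes the cytokine interleukin-6 (chromosome 5, 29968080 to 29969181; 3172 and 324). A further region lay 2.1 kb from Igtp, an interferon-inducible GTPase gene (chromosome 11, 58196825 to 58198068; 3208.50 and 267). The remaining regions of the 10 were nearest to Phkb, Zc2hc1a, Uchl3, Miga2, Mcph1 and Zfand3, with replicate 3 scores from 265 to 328. All 10 scored above 3100 in replicate 2 and are not the strongest by replicate 3 score. Of the shared regions, 2371 scored exactly 3100 in replicate 2 and had a median replicate 3 score of 265.5, against 161 for the 207 regions scored above 3100.

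With scores of exactly 3100 placed highest, a ranking chosen after the data were seen, 11 regions stood at 3100 in both lists. One of them lay 1.6 kb beyond an end of Bcl11a, a zinc-finger factor needed for B cell development (chromosome 11, 24173911 to 24176460). Another lay 0.5 kb from Wdr12, a ribosome assembly gene (chromosome 1, 60070075 to 60071578). The others were nearest to Pms1, Esr1, Tafa2, Krt9, Macroh2a1, Gbe1, Unc5cl, Epg5 and Cecr2, at 2.0 to 234 kb from the nearer gene end.

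The second comparison asks where in the genome the shared regions lie. Ends of protein-coding genes held 693 of the 6133 shared regions (11.3%, exact 95% interval 10.5 to 12.1), which was 3.56 times the 3.18% ± 0.229 (SD) of random placement. Intergenic sequence held 2399 (39.1%, 37.9 to 40.4), below the random 49.8%. Regions inside protein-coding genes made up 40.6%, against 38.9% at random. Regions inside other genes made up 8.98%, against 8.09% (permutation p = 0.0396). The other 3 classes each gave permutation p = 0.0198, two-sided, the smallest the placements can give. The excess inside protein-coding genes was lost when gene ends were widened to 5 kb (ratio 0.99, permutation p = 0.614). Without chromosome X, an alternative added later, the ratio was 1.04, as with all chromosomes, and the permutation p was 0.0792.

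Shared regions and peaks found only in replicate 2 were compared directly, a test chosen after the data were seen. Intergenic sequence held 39.1% of the shared regions and 42.0% of the 68355 replicate 2 peaks without a replicate 3 peak (Fisher exact test, odds ratio 0.887, adjusted exact p = 4.5e-05). Shares at gene ends were 11.3% and 10.6% (adjusted exact p = 0.129), and inside protein-coding genes 40.6% and 38.9% (adjusted exact p = 0.0205). These tests take regions and peaks as units, which are not independent replicates. The peaks found only in replicate 2 had lower scores. Over 10% bins of replicate 2 score, the share at gene ends rose from 4.97% in the lowest bin to 15.7% and 15.6% in the bins that start at 517 and 871, and was 13.9% in the highest. Compared within 10% bins of score, a comparison of replicate 2 peaks added after the data were seen, those with a replicate 3 peak lay at gene ends less often (odds ratio 0.525, 95% interval 0.465 to 0.593) and in intergenic sequence more often (1.31, 1.19 to 1.43). The excess inside protein-coding genes was lost (1.04, 0.954 to 1.13). Within 1% bins, also added later, the odds ratios were 0.461 (0.400 to 0.532), 1.39 (1.26 to 1.54) and 1.056 (0.957 to 1.16). In the highest 10% bin, gene ends held 11.5% of the 5421 peaks with a replicate 3 peak and 20.5% of the 2029 without one.

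The third comparison asks which gene groups carry PU.1. Genes of B cell receptor signalling carried shared regions most often. Of 30 members, 18 had one within 5 kb of an end (60%, exact 95% interval 40.6 to 77.3), against 9.15% of other protein-coding genes (Fisher exact test, odds ratio 14.9, adjusted exact p = 7.58e-11). Grb2, an adaptor protein gene, had a region at chromosome 11, 115711947 to 115713339, with scores of 3100 and 499. Blnk, the adaptor that links Syk to downstream signalling, had 4 shared regions in or within 5 kb of its span. The better ranked of the 2 near a gene end lay at chromosome 19, 40997281 to 40999659 (3100 and 413). Pik3ap1 and Dapp1, both adaptors of phosphoinositide signalling, had regions overlapping a gene end with replicate 3 scores of 258 and 217. In replicate 2 alone, 28 of 30 members of the list had a peak (93.3%, against 61.9% of other genes). The odds ratio there was 8.62 (adjusted exact p = 0.000791), below the 13.3 of ribosomal protein genes. With the merged list it was 7.94.

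Among the always-named genes of this group, Cd79a, which encodes a signalling chain of the receptor, had a region across one gene end (chromosome 7, 24896778 to 24898743; 3100 and 132). Fcgr2b, an inhibitory Fc receptor gene, had one at chromosome 1, 170975514 to 170976688 (3100 and 170). Btk, the tyrosine kinase lost in X-linked agammaglobulinaemia, had one at chromosome X, 134584895 to 134586226 (2762 and 108). Syk had one at chromosome 13, 52582504 to 52584288 (2272 and 94.9). Cd79b and Cd22 had no shared region, and their best replicate 2 peaks scored 2051 and 305.

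B-lineage transcription factor genes carried shared regions at 9 of 29 members (31%, 15.3 to 50.8; odds ratio 4.45, adjusted exact p = 0.00344). Besides Bcl11a, these included Pou2f2 (chromosome 7, 25179691 to 25182254; 3100 and 253), Ebf1, a factor that specifies the B lineage (chromosome 11, 45007531 to 45008638; 3100 and 224), and Tcf3, which encodes the E2A proteins (chromosome 10, 80436701 to 80437979; 2134 and 143). Spi1 itself had a shared region across one end of its span (chromosome 2, 91080578 to 91083665; 2599 and 74.2). Its replicate 3 score is near the lowest of that list, 70.0, and it is not shared with scores of at least 100. The same holds, among others, for the regions of Syk, Il7r, H2-Ab1 and Hmgb2, which also score under 100 in replicate 3. A stronger pair of peaks, chosen after their values were seen, lay 11.8 kb before that end of Spi1, at chromosome 2, 91069850 to 91071198 in replicate 2 (3100) and with a score of 207 in replicate 3. Spib, the gene of the related factor Spi-B, had one at chromosome 7, 44533815 to 44534989 (2413 and 107). With the window widened to the gene body plus 5 kb, 20 of 29 members of the list had a shared region. That was 69.0%, against 15.2% of other genes (odds ratio 12.4, adjusted exact p = 7.01e-10). Longer genes offer a wider window, and this odds ratio was not adjusted for gene length. For regions near gene ends, a logistic model with gene length and neighbour distance gave an odds ratio of 4.51.

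Genes of TLR and NF-kB signalling had shared regions at 10 of 28 members (35.7%, 18.6 to 55.9; odds ratio 5.49, adjusted exact p = 0.000722). In replicate 2 alone the odds ratio of this list was 2.83 (82.1%, against 61.9% of other genes, adjusted exact p = 0.0466). Tlr9 and Tlr4, receptors for unmethylated DNA and for lipopolysaccharide, had regions at one gene end with replicate 3 scores of 323 and 310. Rel and Nfkb1, both NF-kB subunits, had regions scored 113 and 150.1 in replicate 3. MHC class II presentation genes had them at 5 of 14 members (35.7%, 12.8 to 64.9; adjusted exact p = 0.0196), among them Ctss (283 in replicate 3), H2-Ab1 (88.8), and H2-DMa and H2-DMb2, which lie side by side and share 1 region (226). IL-7 and JAK-STAT genes had them at 6 of 22 members (27.3%, 10.7 to 50.2; adjusted exact p = 0.0299), with Socs3 at 227, Mcl1 at 215, Bcl2l1 at 162, Socs2 at 128 and Il7r, the interleukin-7 receptor gene, at 95.5. Without replicate 2 the adjusted exact p was 0.0831 for IL-7 and JAK-STAT genes and 0.0741 for MHC class II genes, and within 1 kb it was 0.0506 and 0.228. Over all alternatives it ran from 0.000982 to 0.195 and from 0.00377 to 0.228. H2-DMa and H2-DMb2 each count as a hit through the same region, so the 5 MHC class II hits are not independent. The regions of Ctss and H2-Ab1 lay outside the gene spans, more than 1 kb from the nearer end. Within 1 kb, 2 of 14 MHC class II members had a region. With scores of at least 100, 3 of 14 did (adjusted exact p = 0.117).

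Myeloid genes had shared regions at 8 of 36 members (22.2%, 10.1 to 39.2; odds ratio 2.82, adjusted exact p = 0.0299). Cd68 and Ncf1 each had 2, with best replicate 3 scores of 417 and 411, and Ncf4 and Tyrobp had scores of 302 and 215. Csf1r and Itgam, both genes of macrophage receptors, had no shared region and best replicate 2 scores of 1004 and 1903. For the myeloid list the adjusted p ran from 0.00966 to 0.164 over the alternatives, the highest within 1 kb.

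Pre-BCR and recombination genes had a shared region at 1 of 16 members, Hmgb2 (6.25%, 0.158 to 30.2; adjusted exact p = 1.00). Rag1, a recombinase gene of that list, had a replicate 2 peak scored 1035 and no replicate 3 peak. The longer lists gave another picture for this group, with 14 of 16 members (87.5%) near a replicate 2 peak (odds ratio 4.31, adjusted exact p = 0.0519) and 14 of 16 near a merged interval (odds ratio 6.17, adjusted exact p = 0.00913). Comparison lists also passed in the merged list. Ribosomal protein genes had 40 of 45 members near a merged interval (88.9%, odds ratio 7.07, adjusted exact p = 6.23e-06). T cell genes had 20 of 26 (76.9%, odds ratio 2.94, adjusted exact p = 0.0231). The merged-list value is thus not particular to the pre-BCR list. For that list the adjusted p ran from 0.00913 to 1.00 over all alternatives.

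None of the comparison lists passed the threshold in the shared regions. T cell genes had a region at 4 of 26 (15.4%, adjusted exact p = 0.404), with Ctla4 at 152 in replicate 3, erythroid genes at 4 of 19 (21.1%, adjusted exact p = 0.157), and ribosomal protein genes at 6 of 45 (13.3%, adjusted exact p = 0.404), with Rps19 at 192 and Rps3 at 189. The erythroid members were Tfrc, Gata1, Hbb-bt and Tal1, with replicate 3 scores of 536, 375.5, 349 and 93.7. The erythroid odds ratio of 2.63 was close to the 2.82 of the myeloid list, which passed with 36 members against 19. The shared regions thus do not set the myeloid list apart from the erythroid one. In replicate 2 alone the odds ratios were 0.845 for erythroid and 3.08 for myeloid genes. Liver and neuron genes had 1 of 24 each, Ahsg and Nefh (4.17%, adjusted exact p = 0.786). In replicate 2 alone, peaks came near 61.9% of all protein-coding genes, and ribosomal protein genes had them at 43 of 45 (95.6%, adjusted exact p = 2.81e-06) and T cell genes at 22 of 26 (84.6%, adjusted exact p = 0.0266).

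With the background held to the 13554 genes that had a replicate 2 peak near an end, an alternative added after the data were seen, B cell receptor signalling had a shared region at 18 of 28 members (64.3%, against 14.8% of other genes; odds ratio 10.4) and TLR and NF-kB signalling at 10 of 23 (43.5%; odds ratio 4.41). Those were the 2 lists past the threshold there; B-lineage transcription factors gave an adjusted p of 0.0524. Within 1 kb of a gene end, 3 lists passed.

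**Figure D2:**
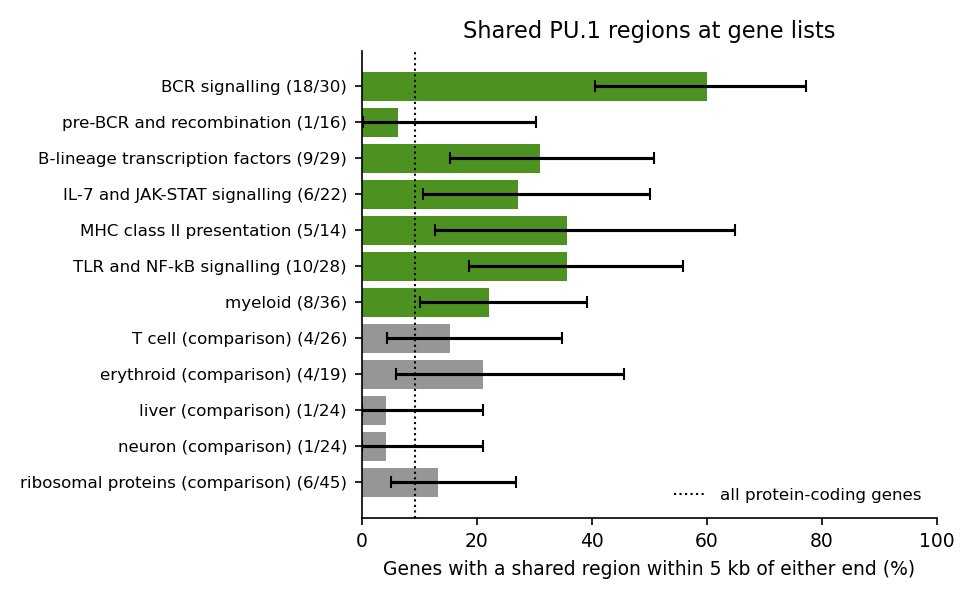
Share of the members of each gene list (x axis, percent) with a shared region within 5 kb of either gene end, with exact 95% intervals as bars and the member counts beside each name; green bars are B cell, immune and myeloid lists, grey bars are comparison lists. The dotted line marks the 9.22% of all protein-coding genes, and B cell receptor signalling stands at 60%.

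The fourth comparison concerns the immunoglobulin loci, whose V, D and J segments are joined during B cell development. The κ light chain locus held 27 shared regions across its segments (chromosome 6, 67555636 to 70726754), against 6.73 ± 2.32 (SD) at random, a ratio of 4.01 (permutation p = 0.0198, two-sided, the smallest the placements can give). A shared region lay within 1 kb of 14 of 162 Vκ segments (8.64%, 4.81 to 14.1; random 0.889%, permutation p = 0.0198). With scores of at least 100 in both lists, 17 shared regions were left (ratio 3.06) and the share of Vκ segments was 4.32%, against 0.71% at random. In replicate 2 alone, 82 of 162 Vκ segments had a peak (50.6%, 42.7 to 58.6; random 9.60%). The segments Igkv10-96 and Igkv10-95, chosen after their values were seen, had peaks of 3100 in replicate 2 and of 272 and 266 in replicate 3.

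The heavy chain locus held 10 shared regions, against 5.85 at random (permutation p = 0.178), and 3 of 183 VH segments had one. In replicate 2 it held 138 peaks against 73.9 (permutation p = 0.0198), and 33 of 183 VH segments had one (18.0%, 12.8 to 24.4; random 9.11%, permutation p = 0.0198). The λ locus held 1 shared region (permutation p = 0.693) and 15 replicate 2 peaks, against 6.04 at random (permutation p = 0.0198). The difference between the loci was not tested.

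In replicate 2, peaks marked functional Vκ segments more often than Vκ pseudogenes, a test chosen after the data were seen. They lay at 65 of 102 functional segments (63.7%) and 17 of 60 pseudogenes (28.3%; Fisher exact test, odds ratio 4.44, adjusted exact p = 0.000228). For shared regions the counts were 13 of 102 and 1 of 60 (adjusted exact p = 0.073). VH segments in replicate 2 gave 15.8% of functional segments and 22.2% of pseudogenes (adjusted exact p = 0.54). At the T cell receptor span of Tra and Trd, replicate 2 peaks lay at 31 of 119 functional V segments (26.1%). They lay at 1 of 17 pseudogenes there (5.88%, odds ratio 5.64, adjusted exact p = 0.182), so the difference is not shown to be particular to κ. V segments of a family can lie side by side and are not independent.

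Around the κ constant segment Igkc (chromosome 6, 70726435 to 70726754), replicate 2 had 3 strong peaks. One lay between Igkj5 and Igkc, where the intronic κ enhancer is known to lie (70725291 to 70726402; score 1925). The next was centred 4.3 kb beyond Igkc (70730497 to 70731693; 2065) and was the only one with a replicate 3 peak (95.7). Another was centred 8.9 kb away, on the side where the 3' κ enhancers are known to lie (70735152 to 70736227; 1511). In the heavy chain locus a replicate 2 peak lay between Ighj4 and Ighm (chromosome 12, 113426920 to 113428097; 1836). A shared region lay 13.5 kb outside Igha, on the side of the known 3' regulatory region (113242100 to 113243307; 2561 and 164). Ighj4, Ighm, Igha and Igkj5 are not covered by the naming rule, and these landmarks and the heavy chain peaks were chosen after their values were seen. Iglc1 and Iglc2 had no peak within 5 kb in either list, and the best replicate 2 peak within 30 kb of Iglc2 was centred 18.9 kb away (chromosome 16, 19178838 to 19180453; 1808).

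**Figure D3:**
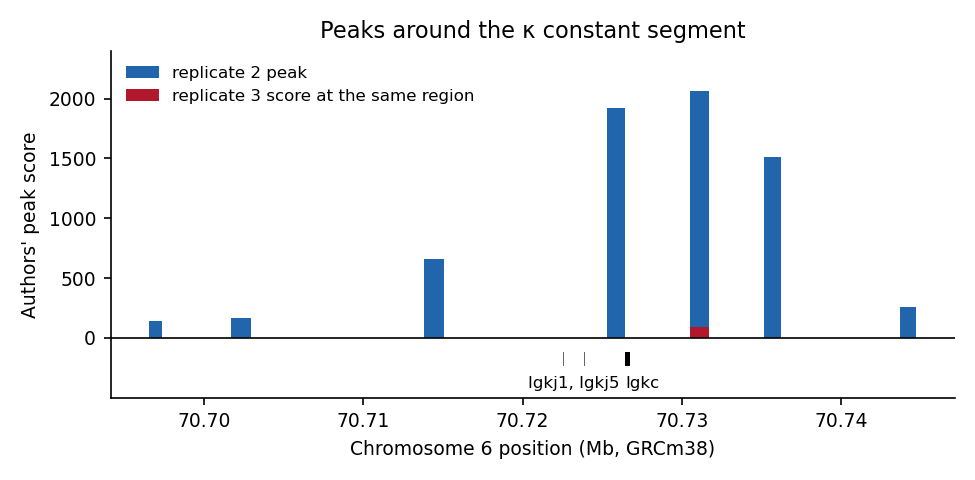
Replicate 2 peaks within 30 kb of Igkc on chromosome 6 (x axis, Mb, GRCm38) by the authors' score (y axis), with the replicate 3 score in red where that list has a peak, and the segments Igkj1, Igkj5 and Igkc drawn below the axis. The scores of both libraries are not on a common scale, and the region at 70730497 to 70731693 is the only one with a replicate 3 peak.

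Chromosome X carried fewer peaks per Mb than the autosomes. Replicate 2 had 15.6 peaks per Mb on X, against 24.8 to 37.8 on the 19 autosomes. Per protein-coding gene it had 2.75 peaks on X, inside the autosomal range of 2.09 to 4.89. The median score was 148 on X, against 212 to 271. A replicate 3 peak was found for 80 of 2661 X peaks of replicate 2 (3.01%, 2.39 to 3.73), against 8.44% of autosomal ones (Fisher exact test, odds ratio 0.336, p = 1.56e-29), a test chosen after the data were seen. The test takes peaks as units, so its p does not cover the spread between chromosomes or libraries. The share on single autosomes ran from 7.24% to 10.1%. X peaks made up 5.17% of the lowest 10% of replicate 2 scores and 1.36% of the highest. Within 1% bins of score, the odds ratio was 0.926 (95% interval 0.633 to 1.36), and 82.0 of the X peaks would have a replicate 3 peak at the shares of their bins, against the 80 seen. Within 10% bins it was 0.747 (0.528 to 1.058). Btk and Gata1 were among the X-linked genes with shared regions. Chromosome Y had 107 replicate 2 peaks with a median score of 92.8.

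**Figure D4:**
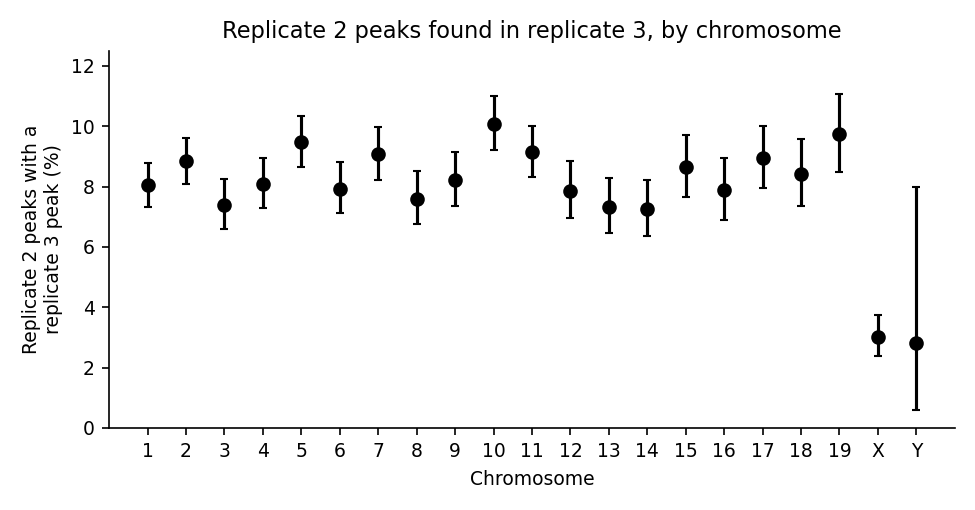
Share of replicate 2 peaks that overlap a replicate 3 peak (y axis, percent) on each chromosome (x axis), with exact 95% intervals as bars. The autosomes lie between 7.24% and 10.1%, and chromosome X lies at 3.01%.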

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

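The tests in this part were chosen after the results were seen, apart from the planned random placements of peaks and the planned shift by 10 kb. The 2 PU.1 libraries share 1 condition, so no explanation that needs a contrast between conditions was tested. The merged list held 14 intervals that overlapped no peak of either library, a signal in a file outside the main comparisons.

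Every replicate 3 peak overlapped a replicate 2 peak. Chance overlap is argued against, since the highest share over 100 random placements was 7.05%, and peaks shifted by 10 kb gave 13.6%. The same peak calls having been deposited in both files is also argued against, since 0 replicate 3 peaks had both ends equal to a replicate 2 peak. What stays open is that replicate 3 may be a shallower or less enriched library of the same binding: 72.8% of the top 10% of replicate 2 peaks by score had a replicate 3 peak, and 0.00805% of the lower 50% did. These lists do not separate depth from enrichment, nor 2 libraries from 1 chromatin sample.

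Chromosome X had fewer replicate 2 peaks per Mb than any autosome, though its 2.75 peaks per gene lay inside the autosomal range of 2.09 to 4.89. Lower gene density as the whole cause is argued against: X had 5.65 genes per Mb, and a line over the 19 autosomes gave 26.9 peaks per Mb at that density (95% prediction interval 20.8 to 33), against 15.6 measured. X peaks of replicate 2 were also found less often in replicate 3, and their lower scores fit this: within 1% bins of replicate 2 score, the odds ratio of X against autosomes was 0.926 (95% interval 0.633 to 1.36). Why the scores are lower is not shown. Another mix of gene ends, gene bodies and intergenic sites as the whole cause is argued against, since the odds ratio pooled over these classes was 0.343 (95% interval 0.274 to 0.429). Copy number of X and weaker binding on X stay open, since neither was tested.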

How the results depend on the processing

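The 100-score, reciprocal-overlap, single-list, merged-list, window, model and 10 kb shift alternatives were planned. Tests with 3100 ranked highest, with a replicate 2 background, with replicate 2 scores of at least 1000, without chromosome X and within bins of score were chosen after the data were seen. Over all alternatives, 185 values kept their direction and side of the threshold or stayed in range, 20 lost the threshold, 10 gained it, 6 moved and 18 turned. The Spearman correlation of the scores was 0.630 for scores of at least 100, 0.765 for reciprocal overlap, 0.643 for the shortened replicate 2 list and 0.770 with 3100 ranked highest; the cause was not tested. The ratio inside protein-coding genes was 0.990 with 5 kb gene ends and 1.04 without chromosome X; the cause was not tested. Of 12 gene lists, 6 passed in the main test, 3 within 1 kb and 2 with the replicate 2 background, where fewer genes enter, and between 4 and 8 with either replicate left out. BCR signalling and TLR and NF-kB signalling passed under all 13 alternatives (adjusted p up to 0.000791 and 0.0466). B-lineage transcription factors passed under 12 (up to 0.0524), myeloid under 9, and IL-7 and MHC class II under 8 each. Ribosomal proteins passed under 3 and T cell genes under 2, all with longer lists. The alternatives reuse the same peaks, so these counts are not separate checks. Every replicate 3 peak is part of a shared region, so leaving out replicate 2 nearly repeats the main test (BCR signalling 18 of 30 in both). The pre-BCR odds ratio turned from 0.656 to 6.17 with the merged list, 4.31 without replicate 3, 1.38 within 1 kb, 2.21 within 50 kb, 1.28 with gene body plus 5 kb and 2.29 with replicate 2 scores of at least 1000 (0.678 without replicate 2; adjusted p from 0.00913 to 1, under 0.05 with the merged list alone). Comparison lists that turned, none past the threshold, were T cell (1.79 to 0.573, scores of at least 100), erythroid (2.63 to 0.845 without replicate 3 and 0.640 with the merged list; 2.72 without replicate 2), liver (0.428 to 1.23 within 50 kb) and ribosomal proteins (1.52 to 0.851 with gene body plus 5 kb and 0.927 with the replicate 2 background); the cause was not tested. Within 10% and 1% bins of score, the odds ratios of shared against replicate 2 only turned from 1.07 to 0.525 and 0.461 at gene ends and from 0.887 to 1.31 and 1.39 for intergenic sequence. The odds ratio of X against autosomes went from 0.336 to 0.747 and 0.926. At the Igl locus the ratio turned from 2.38 to 0 for scores of at least 100, where 0 regions were left, and was 2.04 and 2.48 without replicate 2 and without replicate 3. The Igh ratio was 1.75 and 1.87 without replicate 2 and without replicate 3, and 1.92 with the merged list; VH segments with a peak were 1.64% and 18.0%, and 11.5% with the merged list. More peaks enter in the longer lists. Read depth was not used here, so what depth limits in replicate 3 is not separable from enrichment. Motif, 8-mer and repeat-mask alternatives were not run; of the repeat and contig filter only removal of chromosome Y was.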

Other observations

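All tests in this part were chosen after the data were seen. Gene families, taken as protein-coding symbols that share a letter stem and have at least 15 members, were tested in the same way as the gene lists (152 families, Fisher exact test with Benjamini-Hochberg adjustment). Genes of the Pik stem, mostly phosphoinositide 3-kinase subunits, had a shared region within 5 kb of an end at 9 of 16 members (56.2%, against 9.19% of other genes; odds ratio 12.7, adjusted exact p = 9.02e-05), among them Pik3cd, Pik3cg, Pik3r5 and Pik3ap1. Ptpn genes, which encode protein tyrosine phosphatases, had one at 7 of 17 (41.2%, adjusted exact p = 0.0103), including Ptpn6, Ptpn11 and Ptpn22, and within 1 kb the adjusted exact p was 0.143. Cd genes had one at 26 of 100 (adjusted exact p = 3.2e-05), and Trmt genes, of transfer RNA methylation, at 6 of 16 (adjusted exact p = 0.0411). In replicate 2 alone, 81.0% of Cd genes had a peak (adjusted exact p = 0.000304), while Pik (87.5%, 0.0822), Ptpn (88.2%, 0.0591) and Trmt (87.5%, 0.0822) did not pass, against 61.9% of other genes in these 3 tests. Members of a stem can lie side by side and are not independent. Some hits recur from the gene lists, such as Pik3ap1 and Cd79a of BCR signalling and Cd68 of the myeloid list. The families are thus not separate from those lists.

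Olfactory receptor genes (Olfr) had a shared region at 14 of 1110 members (1.26%, against 9.65% of other genes; adjusted exact p = 4.52e-28) and vomeronasal receptor genes (Vmn) at 1 of 355 (0.282%; adjusted exact p = 3.38e-12). In replicate 2 alone the shares were 15.9% and 10.1%, against 64.4% and 62.8% of other genes. Predicted genes of the Gm stem had one at 40 of 1329 (3.01%). Defensin genes (Defa), which are near-identical copies in tandem, had one at 11 of 29 (37.9%, adjusted exact p = 0.000727), from 7 distinct regions; within 1 kb the share was 0% (adjusted exact p = 1), and in replicate 2 alone it was 58.6% within 5 kb, against 61.9% of other genes (adjusted exact p = 0.786).

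Some 100 kb windows held several shared regions. Windows of 100 kb held up to 6 of them, against a highest window of 3 to 6 over the random placements (permutation p = 0.0198, one-sided). Such windows lay at Cep19 and Nrros (chromosome 16, 32100001 to 32200000), at Ankdd1a, Plekho2 and Pif1 (chromosome 9, 65500001 to 65600000) and at Ptpn22 and Ap4b1 (chromosome 3, 103800001 to 103900000). A window with 5 overlapped Inpp5d, which encodes the phosphatase SHIP-1 (chromosome 1, 87600001 to 87700000). A random placement thus reached the same highest number, and placement ignores gene density and assembly gaps, so clustering is not shown by this single statistic.

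The T cell receptor loci gave a comparison for the immunoglobulin loci. The Tra and Trd span held 71 replicate 2 peaks, against 45.2 at random (permutation p = 0.0198, two-sided, the smallest the placements can give), and 5 shared regions (permutation p = 0.515). Of its 136 V segments, 32 had a replicate 2 peak (23.5%, 16.7 to 31.6; random 8.46%, permutation p = 0.0198), a share not below the 18.0% of VH segments. The Trb span held 15 replicate 2 peaks, against 17.9 (permutation p = 0.495), and 0 shared regions.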
